A study of Homo sapiens with 12 samples.

How the data were processed

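Total RNA of HH, Hut78 and NB4 cells was extracted with TRIzol and libraries were prepared by BGI Genomics, per the labels. The series design states 1 µM ATRA for 6 h and n = 2 for each group. Per the labels, reads were aligned to GRCh38 (hg38), with HISAT named among the tools and no version given. The counting tool, the version of the annotation and the strand used in counting are not stated. The deposited table gives, for 17320 genes with NCBI gene IDs, an expected count per library, which the authors did not normalize. About 86% of these values are whole numbers. Abundances in TPM were also deposited by the authors for each library. The authors' log2 fold change and their q-value, an adjusted p-value, come from DESeq2 per the file headers.

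The counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, from the deposited expected counts of all 12 libraries, with 1 mean for each of the 6 groups of line and treatment. Genes were kept by filterByExpr with the group factor (a minimum of 10 counts in 2 libraries at the median depth, and 15 in total), which left 13668 genes and removed 3652. Libraries were scaled by TMM, with factors from 0.96 to 1.06. The quasi-likelihood fit (glmQLFit, robust) had 6 residual degrees of freedom and 24.1 prior degrees of freedom, and the biological coefficient of variation was 4.15%. Contrasts were ATRA minus control in each line, the differences of these responses between lines, and the controls of the lines for the 2 retinoid lists. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was called, with no minimum fold. The prior count for fitted fold changes was 0.125. The standard error of a log2 fold change is its size divided by the square root of F. For a large fold from a group of few counts, this value can lie below counting error alone.

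Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 2.07 to 5.12. At 12631664 to 15888585 counts per library, 0 counts over a group of 2 libraries allow up to 3 at 95% confidence. The 10 most abundant genes took 4.98% to 7.61% of the counts of a library. Equal replicate numbers were not taken as pairs: deviations of same-numbered control and ATRA libraries correlated across genes at -0.121 in HH, -0.0194 in Hut78 and 0.108 in NB4. A group of 2 libraries allows no test for an outlying library.

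Gene lists were tested with camera at a preset correlation of 0.01 between genes, two-sided, with p-values adjusted by Benjamini-Hochberg over the 81 tests of 27 lists in 3 lines. Lists with fewer than 3 members tested were left out. The correlation was also estimated per list, and fry was run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. Shared changes between lines were tested with Fisher's exact test in each direction. Gene Ontology terms were tested with a one-sided Fisher's exact test over the 13668 genes. GC content and transcript length came from the reference annotation, for 16941 of the 17320 genes. The positions and symbols of 17182 gene IDs were found in the reference table and 138 were not. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

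The comparisons with their tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Fisher's exact tests of changes shared by pairs of lines, the Gene Ontology terms and the tests of single patterns were added later. That rule asked for protein-coding genes where a gene type was given, but no filter on gene type was applied. The rule names, per line, the 12 largest rises and 8 largest falls among genes with a symbol, an adjusted p under 0.05, a change of 2-fold or more, ATRA and control libraries that do not overlap, and at least 1 CPM in the higher group. It adds 13 genes fixed by name, up to 4 members of each list with the smallest adjusted p, 6 genes per direction for each difference between lines, and 20 genes changed the same way in all 3 lines. Some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen. Overlaps with other genes were read from the reference annotation.

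Alternatives were RLE size factors, no filter on low counts (17292 genes), DESeq2 1.42.0 with its own size factors and filtering, a replicate block, leaving out each of the 12 libraries in turn, a minimum fold of 2, and each line or pair of lines fitted alone. The deposited TPM values were tested with limma-trend as log2 of the value plus 1, or plus 0.1, for 12943 genes of 1 TPM or more in at least 2 libraries. They were not scaled by TMM. With 1 library left out, its group holds a lone library that is assumed to vary like the other groups. Added later were the block with the numbers of HH crossed, and counts over genes of 20 CPM or more.

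The tests were tested on simulated data with the dispersions of these libraries over 13668 genes. Of genes of 1 CPM or more in every line changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 91.04%, 98.5% and 100% in HH, 94.03%, 98.5% and 100% in Hut78, and 95.5%, 100% and 100% in NB4. False calls made up 4.46%, 6.25% and 3.90% of all calls. A replicate block raised them to 8.96%, 14.8% and 10.0%. For differences of response of 2-fold, 96.6% to 98.1% were recovered, with 4.28% to 4.91% of calls false. In each line only 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, while 41.6% to 49.6% of genes were called in the data. Genes under 1 CPM in any line were not among those changed. The simulated shares of false calls therefore cannot be carried over to the calls in the data.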

Results

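RNA from 3 human cell lines was sequenced with and without all-trans retinoic acid (ATRA), the natural ligand of the retinoic acid receptors, given at 1 µM for 6 h. HH and Hut78 are lines of cutaneous T-cell lymphoma, and NB4 is a line of acute promyelocytic leukemia, a disease treated with ATRA. NB4 carries the PML-RARA fusion, whose reads count towards PML and RARA. Each line had a control group and an ATRA group of 2 libraries, 12 libraries in 6 groups. The labels do not say whether the replicates were separate cultures. The libraries held 14589133 and 13848978 counts for the HH controls, 12631664 and 13257596 for HH with ATRA, 15593837 and 15888585 for the Hut78 controls, 15627083 and 15867508 for Hut78 with ATRA, 15836345 and 15633150.0 for the NB4 controls and 15731228 and 15097356 for NB4 with ATRA. Replicates correlated across genes at a Pearson r of 0.997 to 0.998 of their log2 CPM (counts scaled by library size), a relation over genes that are not independent replicates. The table held 17320 genes, of which 13668 had enough counts to be tested and 3652 did not.

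Every change is ATRA over the control of the same line, tested with edgeR's quasi-likelihood F-test and adjusted by Benjamini-Hochberg (BH) over the 13668 genes, with 2 libraries per group. A log2 fold change is given ± a standard error derived from F, and a level in CPM as the mean ± SD of the 2 libraries of a group. For a large fold from a group of few counts, that standard error understates the uncertainty and can lie below counting error alone. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the fold is the ratio of the pooled counts with an exact binomial 95% interval. These bounds and intervals cover counting error only. Counts of genes changed 2-fold or more use the fitted fold, which for a gene at 0 in a group can exceed 2 where its bound does not. The labels state neither a vehicle nor a treatment time for the controls, so a change can include an effect of the solvent. Positions are on GRCh38. The strand used in counting was not stated, so reads of overlapping genes on opposite strands cannot be parted.

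The HH comparison asked which genes ATRA changed within 6 h in a cutaneous T-cell lymphoma line. ATRA raised HIC1 and ASB2, and known retinoic acid responsive genes rose as a group. Genes of DNA replication, mitosis and ribosome making fell together. The retinoid enzyme genes CYP26A1, CYP26B1 and DHRS3 stayed at or near 0 counts. Of the 13668 genes, 6745 changed (49.3%), with 3706 higher and 3039 lower, and 1095 of them by 2-fold or more, with 958 higher and 137 lower.

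HIC1, which encodes a zinc-finger repressor of transcription (NCBI gene 3090, chromosome 17, 2054215 to 2063241), rose 13.6-fold in HH, from 34.7 ± 4.13 to 474 ± 5.88 CPM (log2 fold change 3.77 ± 0.07, adjusted p = 7.47e-26). Its span overlaps SMG6, so reads of SMG6 can add to it. ASB2, the substrate-binding part of a ubiquitin ligase (NCBI gene 51676, chromosome 14, 93934160 to 93976739), rose 3.85-fold, from 113 ± 6.56 to 434 ± 12.1 CPM (adjusted p = 1.18e-22). STRA6, the cell-surface receptor that takes up retinol, rose at least 3.71-fold from 0 to 0.399 CPM (adjusted p = 0.000666). CD38, an enzyme that cleaves NAD, rose 5.20-fold (95% interval 1.45 to 28.2), and its call was lost on TPM values with a pseudocount of 1 (adjusted p = 0.117) and without control replicate 2 (adjusted p = 0.171) or ATRA replicate 2 (0.129). TGM2, a transglutaminase, rose at least 1.48-fold (adjusted p = 0.0311), a call lost with DESeq2 (0.0604), on TPM values with a pseudocount of 1 (0.29), and without control replicate 1 (0.126), control replicate 2 (0.117), ATRA replicate 1 (0.0726) or ATRA replicate 2 (0.0684). CYP26A1 had 0 counts in the controls and 3 with ATRA, CYP26B1 had 0 in all 4 libraries and DHRS3 had 1 with ATRA, so no fold can be given. The receptor genes RARA (0.14 ± 0.06, adjusted p = 0.0521), RARB (0.439), RARG (1) and RXRA (0.166) passed no threshold, and neither did CRABP2, which carries retinoic acid to the receptors (0.464).

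The largest rises in HH began from genes at or near 0. GZMM, granzyme M of cytotoxic lymphocytes (NCBI gene 3004, chromosome 19, 544053 to 549922), rose at least 64.6-fold to 6.87 ± 1.18 CPM from 0 counts (adjusted p = 2.66e-13). LZTFL1, whose span overlaps the gut-homing receptor CCR9, rose at least 40.8-fold, SETBP1 at least 13.4-fold and TFEC at least 10.8-fold. GPR34, within the span of CASK, rose 141-fold (95% interval 24.9 to 5629.7). GPR35, a G-protein-coupled receptor, rose 30.6-fold (4.94 ± 0.21), RNF207, beside ICMT, 30.3-fold, RAB37, overlapping CD300LF, 28.7-fold, and ACKR3, a scavenging chemokine receptor, 27.4-fold. FGG, the gamma chain of fibrinogen, rose 35.6-fold (95% interval 5.95 to 1451). The adjusted p of these rises was 2.68e-05 or lower.

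Among changes of 2-fold or more, falls in HH were fewer and smaller than rises. The cytokine gene OSM reached 0.0696 of its control level (95% interval 0.0139 to 0.216). GPR55 fell 13.2-fold (-3.72 ± 0.43), the membrane protein gene EMP1 6.20-fold and the clock repressor BHLHE41, which overlaps SSPN, 6.08-fold. SGK3 fell 12.1-fold, a call lost with a replicate block (adjusted p = 0.0543), and its reads are shared with the readthrough gene C8orf44-SGK3. HSPE1-MOB4, a readthrough of HSPE1 and MOB4, was at least 10.8-fold lower. The histone gene H4C12, 1 of many near-identical copies, was at least 14.7-fold lower, a call lost with no filter (0.0531) and without control replicate 2 (adjusted p = 0.0877), ATRA replicate 1 (0.0536) or ATRA replicate 2 (0.0592).

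Chromosome 19 held 4 neighbouring genes that rose together in HH, picked out after their values were seen. CDC34, an E2 ubiquitin-conjugating enzyme (chromosome 19, 531720 to 542088), rose from 54.2 to 354 CPM (2.71 ± 0.06, adjusted p = 2.27e-25). GZMM is the next gene along the strand. BSG, basigin (chromosome 19, 560804 to 583498), rose from 341 to 7301 CPM (4.42 ± 0.07, adjusted p = 1.11e-29). HCN2, an ion channel (chromosome 19, 589881 to 617159), rose from 5.78 to 42.0 CPM (2.86 ± 0.13, adjusted p = 8.96e-18). In Hut78 their log2 fold changes were -0.21 for CDC34, -0.21 for GZMM, -0.16 for BSG and -0.75 for HCN2, and the responses differed from HH at adjusted p = 9.27e-22, 2.22e-12, 1.14e-26 and 2.44e-14. In NB4 they were -0.20, 0.60, -0.32 and -0.14, with differences from HH at adjusted p = 3.13e-21, 0.00296, 1.23e-27 and 0.00488. With 0 counts of GZMM in the HH controls, the size of its differences from HH is not fixed. GZMM and HCN2 reached 2.28% and 0.193% of the level per kb of the gene before each, so reads running on from CDC34 and BSG can add to them. Nearby, FSTL3 also rose in HH (1.58 ± 0.14, adjusted p = 9.6e-11), and its response differed from Hut78 (0.000631) and NB4 (8.06e-08). TPGS1 (0.52 ± 0.17, adjusted p = 0.01) and PALM (from 0 to 0.159 CPM, 0.0337) rose as well. POLRMT (0.02) and RNF126 (-0.32), between HCN2 and FSTL3, did not rise.

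**Figure D1:**
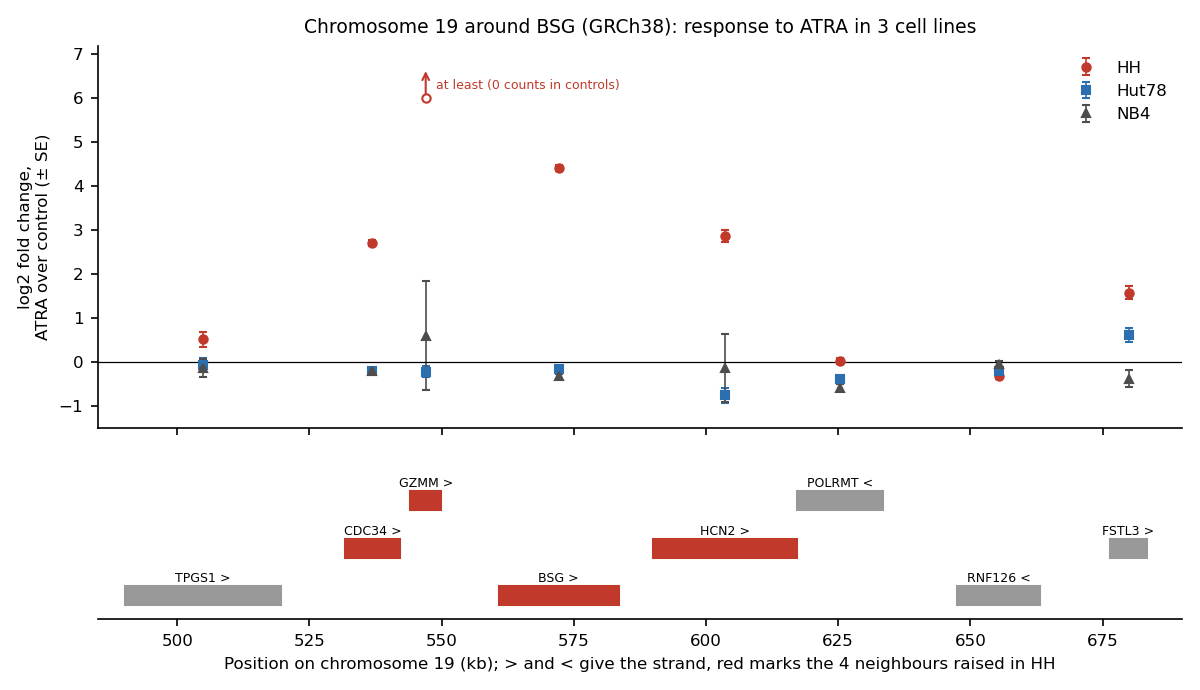
Log2 fold change of ATRA over control (± SE, n = 2 libraries per group) for genes around BSG on chromosome 19 of GRCh38, with position in kb on the x axis and 1 symbol per cell line. In HH, CDC34 (2.71), BSG (4.42) and HCN2 (2.86) rose with GZMM, drawn as a lower bound, while POLRMT beside them lay at 0.02. FSTL3 (1.58) and TPGS1 (0.52) also rose in HH.

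Of 29 gene lists fixed beforehand, 27 had members tested, and limma's camera compared each with all other genes in each line, 81 tests adjusted together by BH. The mitochondrially encoded genes and the erythroid identity list had 0 members tested in any line. HH called 8 lists, 3 higher and 5 lower. In the list of known retinoic acid responsive genes 15 rose and 1 fell of 24 tested, 16 and 1 adjusted over the list alone (adjusted p = 0.000999), with a median log2 fold change of 1.28, or 0.95 with genes at 0 in a group set to their bound. Its members PTGER4, a prostaglandin receptor, and IRF1, an interferon regulator, had log2 fold changes of -1.52 ± 0.07 and 1.52 ± 0.12. Among retinoid receptors and co-regulators 7 rose and 0 fell of 16 tested, 7 and 0 adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.0816 with an estimated correlation). NRIP1, a co-repressor of nuclear receptors, rose 8.94-fold and the co-activator NCOA1 1.37-fold. In the gut homing list 5 rose and 0 fell of 8 tested, 5 and 0 adjusted over the list alone (adjusted p = 0.00733, and adjusted p = 0.103 with an estimated correlation), and its median was 1.43, or 1.24 with bounds. GPR15 rose from 227 ± 15.7 to 731 ± 16.2 CPM, and the integrin genes ITGA4 (1.53 ± 0.08) and ITGB7 (1.33 ± 0.08) rose as well.

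Cell-cycle genes fell in HH. In the list of G2/M and mitosis 0 rose and 26 fell of 29 tested, 0 and 26 adjusted over the list alone (adjusted p = 3.88e-13), including the phosphatase gene CDC25A (-1.35 ± 0.06) and the checkpoint gene MAD2L1 (-1.07 ± 0.07). In the list of G1/S and DNA replication 3 rose and 32 fell of 40 tested, 3 and 33 adjusted over the list alone (adjusted p = 4.84e-12). CDC6, which loads the replicative helicase, fell from 105 ± 2.85 to 41.1 ± 0.662 CPM, CCND2 (cyclin D2) fell 1.93-fold, and the cell-cycle inhibitor CDKN1B rose 2.07-fold. Among genes of MYC and ribosome biogenesis 3 rose and 22 fell of 28 tested, 3 and 22 adjusted over the list alone (adjusted p = 1.94e-09). MYC fell 1.79-fold, from 276 ± 2.16 to 154 ± 6.00 CPM, the polyamine enzyme gene ODC1 2.40-fold, and MXD4, an antagonist of MYC, rose 4.75-fold. In cholesterol synthesis 2 rose and 20 fell of 23 tested, 2 and 20 adjusted over the list alone (adjusted p = 3.14e-09, and adjusted p = 0.0726 with an estimated correlation), with HMGCS1 at -1.23 ± 0.06. In the list of unfolded protein response and integrated stress 1 rose and 15 fell of 20 tested, 1 and 15 adjusted over the list alone (adjusted p = 9.94e-05, and adjusted p = 0.0759 with an estimated correlation). PSAT1, of serine synthesis, fell 2.48-fold and the stress factor ATF3 3.56-fold, while DDIT4, an inhibitor of mTOR signalling, rose 3.91-fold.

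The other lists were not called in HH. Fitted without the other lines, HH gained calls, all higher, for apoptosis regulators (adjusted p = 0.0036), granulocytic differentiation (0.00148) and primary granule genes (5.92e-05). Retinoid metabolism and transport had 2 higher and 2 lower of 15 (1 and 1 adjusted over the list alone, adjusted p = 0.639), with a fall of FABP5, a lipid carrier that also binds retinoic acid (-0.77 ± 0.06). Skin homing of lymphocytes had 4 higher and 3 lower of 11 (5 and 3 adjusted over the list alone, adjusted p = 0.831), where CCR7 rose 1.86-fold. The cutaneous T-cell lymphoma markers had 4 higher and 0 lower of 16 (2 and 0 adjusted over the list alone, adjusted p = 0.598), among them TOX (0.94 ± 0.06). T-cell identity had 9 higher and 3 lower of 19 (10 and 4 adjusted over the list alone, adjusted p = 0.174), including a rise of CD4 (0.42 ± 0.06). T-cell activation and checkpoint had 6 higher and 4 lower of 23 (6 and 4 adjusted over the list alone, adjusted p = 0.891), and T-helper cytokines and regulators 5 higher and 3 lower of 19 (5 and 3 adjusted over the list alone, adjusted p = 0.974). Granulocytic differentiation had 8 higher and 0 lower of 31 (8 and 0 adjusted over the list alone, adjusted p = 0.289), with a rise of GFI1, a repressor that guides granulocytes (2.50 ± 0.07). Primary granule and promyelocyte genes had 4 higher and 0 lower of 18 (4 and 0 adjusted over the list alone, adjusted p = 0.221), with a rise of MYB (0.87 ± 0.05). Apoptosis regulators had 15 higher and 3 lower of 35 (15 and 3 adjusted over the list alone, adjusted p = 0.0688). The interferon list had 11 higher and 3 lower of 38 (11 and 3 adjusted over the list alone, adjusted p = 0.188), the p53 targets 5 higher and 0 lower of 17 (5 and 0 adjusted over the list alone, adjusted p = 0.131), with XPC at 1.20 ± 0.07, and the NF-kB list 6 higher and 6 lower of 24 (6 and 6 adjusted over the list alone, adjusted p = 0.918), with REL at 0.97 ± 0.07.

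Coagulation and fibrinolysis had 3 higher and 3 lower of 15 (3 and 3 adjusted over the list alone, adjusted p = 0.755) in HH, the liver X receptor targets 3 higher and 2 lower of 11 (3 and 2 adjusted over the list alone, adjusted p = 0.873), with SREBF1, a regulator of lipid synthesis, at 1.38 ± 0.05, and the immediate early genes 5 higher and 4 lower of 20 (5 and 4 adjusted over the list alone, adjusted p = 0.974). Among markers of other cells, myeloid identity had 1 higher and 0 lower of 11 (1 and 0 adjusted over the list alone, adjusted p = 0.92), B-cell identity 2 higher and 0 lower of 7 (2 and 0 adjusted over the list alone, adjusted p = 0.552), epithelial identity 1 higher and 0 lower of 8 (1 and 0 adjusted over the list alone, adjusted p = 0.918) and fibroblast identity 2 higher and 0 lower of 6 (2 and 0 adjusted over the list alone, adjusted p = 0.553). The median, mean and test differed in sign for retinoid metabolism (median 0.00, mean 0.77, test lower), NF-kB (0.00, 0.06, lower) and fibroblast identity (0.28, -0.27, higher). Genes of 0.5 to 5 CPM in HH had a median log2 fold change of 0.47 (SE 0.0176 by bootstrap, 1824 genes), against -0.03 in 7432 genes of 20 CPM or more. With p adjusted over those 7432 genes alone, 2286 rose and 2682 fell, and in HH fitted alone 3392 rose and 3455 fell. At 2-fold or more rises outnumbered falls at both levels, with 232 against 48 among genes of 20 CPM or more and 391 against 33 among genes of 0.5 to 5 CPM.

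**Figure D2:**
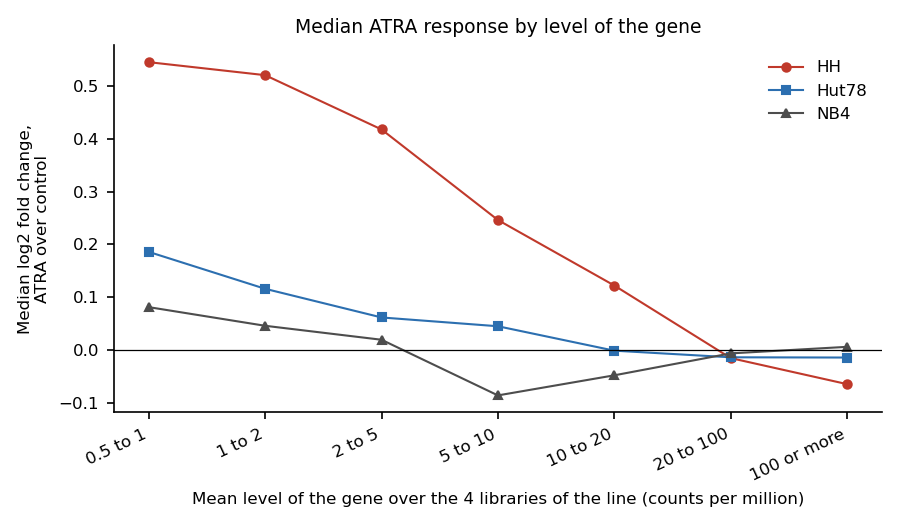
Median log2 fold change of ATRA over control (y axis) against the mean level of the gene in its line in CPM (x axis, in bins), 1 line per cell line. In HH the median was 0.55 for genes of 0.5 to 1 CPM and -0.07 for genes of 100 CPM or more, while Hut78 and NB4 stayed between -0.09 and 0.19.

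In Hut78, another line of cutaneous T-cell lymphoma, the question was the same. ATRA raised the retinoid genes CYP26A1, CYP26B1, DHRS3 and STRA6, and ASB2. Interferon genes and targets of the liver X receptor rose as groups, while genes of MYC and ribosome biogenesis fell. The T-cell genes LAT, LEF1 and CD5 fell, in a T-cell identity list with 5 higher and 7 lower of 19 that was not called. In all, 5683 of 13668 genes changed (41.6%), 2882 higher and 2801 lower, and 1093 of them by 2-fold or more, with 718 higher and 375 lower.

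CYP26B1, a cytochrome P450 that breaks down retinoic acid (NCBI gene 56603, chromosome 2, 72129238 to 72147862), rose 84.7-fold in Hut78, from 0.542 ± 0.00580 to 46.6 ± 1.94 CPM (log2 fold change 6.40 ± 0.18, adjusted p = 2.55e-22). Its relative CYP26A1 (NCBI gene 1592, chromosome 10, 93073475 to 93077885), whose span overlaps CYP26C1, rose 20.6-fold, from 1.45 ± 0.186 to 29.98 ± 3.43 CPM (4.37 ± 0.17, adjusted p = 3.64e-19). DHRS3, which turns retinaldehyde into retinol (NCBI gene 9249, chromosome 1, 12567910 to 12618210), rose 11.99-fold, from 21.9 ± 1.47 to 262 ± 18.6 CPM. STRA6 (NCBI gene 64220, chromosome 15, 74179466 to 74212267) rose 6.16-fold, from 43.8 ± 0.980 to 269.9 ± 3.96 CPM. ASB2 rose 56.7-fold, from 7.04 ± 0.0754 to 399.8 ± 22.7 CPM (5.83 ± 0.08, adjusted p = 2.4e-31), and CD38 (NCBI gene 952, chromosome 4, 15777564 to 15855988) 9.05-fold, from 83.8 ± 0.805 to 759 ± 42.8 CPM. HIC1 rose 6.66-fold and TGM2 (NCBI gene 7052, chromosome 20, 38127385 to 38166508) 24.7-fold. Among the receptors, RARB, whose span overlaps TOP2B, rose 24.6-fold (95% interval 4.01 to 1012) and RARA 1.47-fold, from 60.6 ± 1.12 to 89.04 ± 4.82 CPM, while RXRA fell 2.16-fold, from 39.4 ± 0.0809 to 18.2 ± 2.58 CPM, and RARG 1.57-fold (adjusted p = 0.00142, or 0.131 on TPM values with a pseudocount of 0.1). CRABP2 was not called (adjusted p = 0.729).

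NRIP1, the co-repressor of nuclear receptors (NCBI gene 8204, chromosome 21, 14818843 to 15068251), had 0 counts in the Hut78 controls and 44.9 ± 0.0112 CPM with ATRA, at least 497-fold higher (adjusted p = 4.61e-23). ABCA1, which exports cholesterol, rose 317-fold (95% interval 56.5 to 12559), BNIP5 258-fold (95% interval 45.98 to 10249.9) and CFI, a protease of the complement system, 193-fold (95% interval 65.5 to 936). From 0 counts, the short-chain fatty acid receptor FFAR3 rose at least 40.7-fold, the B-cell lectin CD22 at least 17.4-fold, TMEM235 at least 17.1-fold, PLB1 at least 16.8-fold and ATP6V0A4, which overlaps TMEM213, at least 15.4-fold. LGALS12, a galectin, rose at least 13.7-fold and COL26A1, a collagen, at least 13.3-fold. UBD, a ubiquitin-like modifier, rose 159.8-fold (7.32 ± 0.30). The keratin gene KRT80 fell 51.5-fold, from 41.8 ± 1.81 to 0.802 ± 0.258 CPM (-5.69 ± 0.18, adjusted p = 1.27e-20). MYCN fell 19.6-fold, KLF2, a factor of resting T cells, 16.3-fold, INSM1, which overlaps CFAP61, 14.3-fold, TSBP1, which overlaps BTNL2, 13.6-fold, HS3ST3B1 11.5-fold and CST7 (cystatin F) 11.1-fold, and AARD reached 0.0513 of its control level (95% interval 0.00600 to 0.198).

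In Hut78, camera called 12 lists, 10 higher and 2 lower. Of the known retinoic acid responsive genes 18 rose and 2 fell of 24 tested, 18 and 2 adjusted over the list alone (adjusted p = 1.1e-10). Of the retinoid receptors and co-regulators 9 rose and 3 fell of 16 tested, 10 and 3 adjusted over the list alone (adjusted p = 0.0496, and adjusted p = 0.129 with an estimated correlation), with the co-activator NCOA3 at 0.92 ± 0.06. That call was lost without ATRA replicate 1 (adjusted p = 0.0658), control replicate 1 (0.0604) or control replicate 2 (0.0547), and with another normalization (0.0528). Of the liver X receptor targets 8 rose and 0 fell of 11 tested, 8 and 0 adjusted over the list alone (adjusted p = 1.31e-06), including the cholesterol exporter ABCG1 (1.87 ± 0.10), SREBF1 (1.74 ± 0.06) and the desaturase SCD (1.13 ± 0.05). Of the interferon genes 24 rose and 2 fell of 38 tested, 25 and 2 adjusted over the list alone (adjusted p = 1.76e-08). IRF1 rose from 77.3 ± 0.108 to 208 ± 0.989 CPM and IRF8 7.59-fold. Of the NF-kB genes 13 rose and 2 fell of 24 tested, 13 and 2 adjusted over the list alone (adjusted p = 0.00096, and adjusted p = 0.179 with an estimated correlation), with the inhibitor NFKBIA at 1.09 ± 0.06 and the adhesion gene ICAM1 at 1.73 ± 0.07. Of the apoptosis regulators 13 rose and 4 fell of 35 tested, 14 and 5 adjusted over the list alone (adjusted p = 0.0147, and adjusted p = 0.0781 with an estimated correlation), including the death ligand TNFSF10 (1.21 ± 0.06) and BMF (2.04 ± 0.11).

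Lymphocyte genes moved both ways in Hut78. In T-cell activation and checkpoint 12 rose and 4 fell of 23 tested, 13 and 5 adjusted over the list alone (adjusted p = 0.00733, and adjusted p = 0.142 with an estimated correlation), led by TNFRSF9 (2.24 ± 0.09), CD69 (2.06 ± 0.10) and TNFRSF4 (3.35 ± 0.21). In gut homing 6 rose and 2 fell of 8 tested, 6 and 2 adjusted over the list alone (adjusted p = 0.00815, and adjusted p = 0.0973 with an estimated correlation), where ITGB7 rose 5.52-fold and CCR2 fell 4.10-fold. In skin homing 1 rose and 4 fell of 11 tested, 1 and 4 adjusted over the list alone (adjusted p = 0.0252, and adjusted p = 0.105 with an estimated correlation). CCR4 fell from 153 ± 3.77 to 60.2 ± 1.57 CPM and SELPLG, the ligand of selectins, 2.91-fold. The skin homing call was lost without ATRA replicate 1 (adjusted p = 0.0854), ATRA replicate 2 (0.101) or control replicate 2 (0.0639), with a replicate block (0.0617) and with no filter (0.068). Of the granulocytic genes 12 rose and 3 fell of 31 tested, 12 and 3 adjusted over the list alone (adjusted p = 0.00383, and adjusted p = 0.105 with an estimated correlation), with the integrin gene ITGAX at 5.92 ± 0.22. In B-cell identity 4 rose and 1 fell of 7 tested, 4 and 1 adjusted over the list alone (adjusted p = 0.0088, and adjusted p = 0.184 with an estimated correlation), with FCER2 (CD23) at 4.15 ± 0.14, and with no filter the call was lost (0.0647). In MYC and ribosome biogenesis 2 rose and 20 fell of 28 tested, 2 and 20 adjusted over the list alone (adjusted p = 5.91e-07), and MYC itself fell 1.42-fold, from 547 ± 23.8 to 385 ± 5.23 CPM.

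Lists not called in Hut78 held changed genes as well. Fitted without the other lines, Hut78 gained calls for retinoid metabolism and transport (higher, adjusted p = 3.06e-11), T-cell identity (lower, 0.000896) and fibroblast identity (higher, 0.0396). Retinoid metabolism and transport had 4 higher and 2 lower of 15 (4 and 3 adjusted over the list alone, adjusted p = 0.12). T-cell identity had 5 higher and 7 lower of 19 (5 and 7 adjusted over the list alone, adjusted p = 0.0688). LAT, an adaptor of the T-cell receptor, fell 3.23-fold, from 254 ± 2.12 to 78.5 ± 2.41 CPM, LEF1 2.35-fold and CD5 2.16-fold. CD3E, in contrast, had 2287 and 2291 counts in the controls and 2920 and 3298 with ATRA. The cutaneous T-cell lymphoma markers had 6 higher and 5 lower of 16 (6 and 5 adjusted over the list alone, adjusted p = 0.974), with falls of BCL11B (-1.16 ± 0.07) and GATA3 (-0.67 ± 0.06). T-helper cytokines and regulators had 7 higher and 5 lower of 19 (7 and 5 adjusted over the list alone, adjusted p = 0.308), with rises of SOCS3, an inhibitor of cytokine signalling (3.26 ± 0.09), and of STAT3 (0.82 ± 0.05). Coagulation and fibrinolysis had 3 higher and 4 lower of 15 (3 and 4 adjusted over the list alone, adjusted p = 0.953). G1/S and DNA replication had 10 higher and 8 lower of 40 (10 and 8 adjusted over the list alone, adjusted p = 0.92), with CDKN1A, the p21 inhibitor, at 2.60 ± 0.25. G2/M and mitosis had 4 higher and 8 lower of 29 (4 and 8 adjusted over the list alone, adjusted p = 0.533), cholesterol synthesis 6 higher and 3 lower of 23 (6 and 3 adjusted over the list alone, adjusted p = 0.639) and unfolded protein response 7 higher and 2 lower of 20 (7 and 2 adjusted over the list alone, adjusted p = 0.12).

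Primary granule genes had 2 higher and 2 lower of 18 (2 and 2 adjusted over the list alone, adjusted p = 0.974) in Hut78, the p53 targets 5 higher and 3 lower of 17 (5 and 3 adjusted over the list alone, adjusted p = 0.268), with TP53INP1 at 2.67 ± 0.15, and the immediate early genes 5 higher and 5 lower of 20 (5 and 5 adjusted over the list alone, adjusted p = 0.858), with JUN at 1.95 ± 0.10. Myeloid identity had 0 higher and 1 lower of 11 (0 and 1 adjusted over the list alone, adjusted p = 0.347), epithelial identity 2 higher and 3 lower of 8 (2 and 3 adjusted over the list alone, adjusted p = 0.656) and fibroblast identity 4 higher and 0 lower of 6 (4 and 0 adjusted over the list alone, adjusted p = 0.0706). Signs differed between median, mean and test for the lymphoma markers (0.15, 0.65, lower), T-cell identity (-0.06, 0.00, lower), coagulation (0.12, 0.50, lower), G1/S (-0.02, 0.10, higher), cholesterol synthesis (-0.03, 0.09, higher) and epithelial identity (-0.12, 0.04, lower). DESeq2 called 4165 genes in Hut78, 4142 of them also called by edgeR in the same direction.

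For NB4, the question was how a promyelocytic leukemia line responds to ATRA at the same dose and time. Genes of the maturing granulocyte rose, among them NCF1, S100A9 and PRAM1, and most genes of the promyelocyte's primary granules fell, among them CTSG and MPO. TGM2 had the largest fitted rise. Interferon, apoptosis and liver X receptor genes rose as groups. In all, 6783 of 13668 genes changed (49.6%), 3427 higher and 3356 lower, and 1726 of them by 2-fold or more, with 1034 higher and 692 lower. On the deposited TPM values (transcript abundances scaled by length and depth), 2429 rose and 3645 fell, a share of rises of 40.0% against 50.5% on counts.

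TGM2 rose from 0.255 ± 0.00249 to 2973 ± 3.49 CPM (log2 fold change 13.46 ± 0.11, adjusted p = 1.66e-36) in NB4. The controls held so few counts of TGM2 that the ± 0.11 lies below counting error. CD38 rose 15.6-fold, from 23.5 ± 0.229 to 367 ± 3.62 CPM (3.96 ± 0.07, adjusted p = 5.64e-29), ASB2 27.8-fold, from 4.40 ± 0.318 to 123 ± 1.46 CPM, and HIC1 62.6-fold, from 0.926 ± 0.0361 to 58.5 ± 2.21 CPM. Among retinoid enzymes, DHRS3 rose 94.7-fold, from 0.928 ± 0.325 to 88.4 ± 1.64 CPM, CYP26A1 69.3-fold, from 0.192 ± 0.00186 to 13.8 ± 0.528 CPM, and CYP26B1 161-fold (95% interval 44.3 to 1339). STRA6 rose 3.31-fold, from 8.75 ± 1.08 to 28.96 ± 0.0829 CPM. The receptor genes RARB (6.10 ± 0.39, from 4 counts in the controls), RARG (1.77 ± 0.38) and RARA (0.39 ± 0.07) rose. RXRA fell 2.14-fold, from 109 ± 2.46 to 51.01 ± 0.812 CPM (adjusted p = 8.58e-15). CRABP2 was not called (adjusted p = 0.477).

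**Figure D3:**
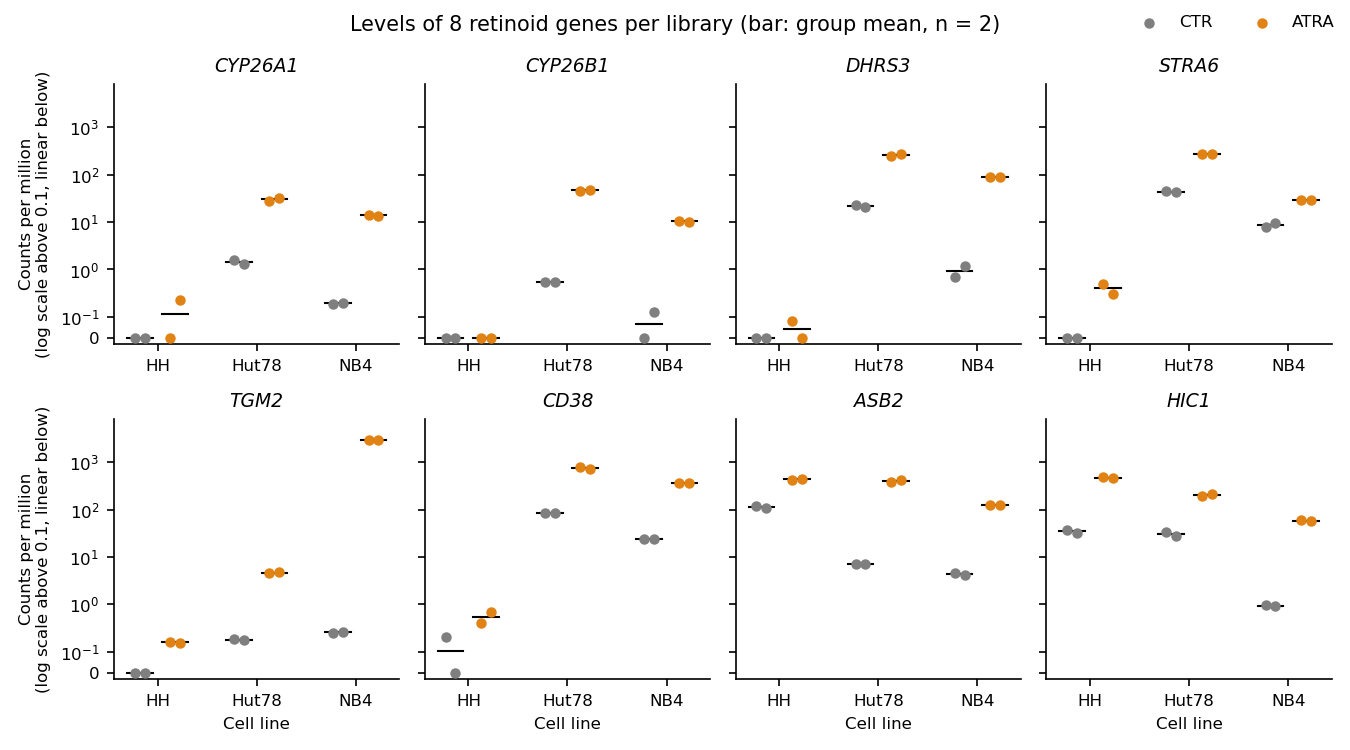
CPM (log scale above 0.1, linear below) of 8 retinoid genes in each of the 12 libraries, in grey for controls and orange for ATRA, with a bar at the mean of the 2 libraries of a group. CYP26A1, CYP26B1 and DHRS3 rose in Hut78 and NB4 and stayed at 3 counts or fewer in HH, while HIC1 and ASB2 rose in all 3 lines.

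PTGES, prostaglandin E synthase, rose at least 706-fold from 0 counts to 67.6 CPM in NB4, SELP (P-selectin) at least 446-fold, ARL14EPL at least 335-fold and MECOM, a zinc-finger transcription factor, at least 136-fold. CEACAM1, whose span overlaps CEACAM8, CXCL17 and LIPE, rose at least 381-fold. The Src-family kinase FGR rose 4789.9-fold (95% interval 1326 to 39558) and the chemokine CCL24 1998-fold (95% interval 683 to 9689). CRISP3, a protein of secondary granules, rose at least 119-fold, PELATON at least 114-fold and DAAM2 at least 101-fold. The defensin gene DEFA3 rose 2526-fold (95% interval 699 to 20863), though its reads cannot be parted from those of its near copies DEFA1 and DEFA1B. STAB1, which overlaps NT5DC2, fell to 0.00622 of its control level (95% interval 0.000157 to 0.0352), CECR2, which overlaps SLC25A18, to 0.0203 of its control level (95% interval 0.000506 to 0.118) and MS4A2, the beta chain of the IgE receptor, to 0.0243 of its control level (95% interval 0.00290 to 0.0906). CYTL1 fell 92.8-fold, from 35.3 ± 3.59 to 0.371 ± 0.0363 CPM, EMILIN2 43.00-fold, IRS1, which relays insulin signals, 40.5-fold, the acetylcholine-making CHAT 38.7-fold and NOG, which blocks bone morphogenetic proteins, 34.3-fold.

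Camera called 10 lists in NB4, 8 higher and 2 lower. In granulocytic differentiation 22 rose and 7 fell of 31 tested, 22 and 7 adjusted over the list alone (adjusted p = 3.14e-09). NCF1, a subunit of the oxidase that makes superoxide, rose from 5.43 ± 0.0375 to 1651 ± 28.2 CPM (8.25 ± 0.09, adjusted p = 6.39e-34), with reads that its pseudogenes can share. The calcium-binding S100A9 rose from 0.896 ± 0.370 to 253 ± 12.7 CPM, the adaptor PRAM1 20.1-fold and TNFAIP2 13.8-fold. In the primary granule and promyelocyte list 4 rose and 13 fell of 18 tested, 4 and 13 adjusted over the list alone (adjusted p = 0.00096), with a median of -1.55 and a mean of -0.15. CTSG, cathepsin G, fell 27.5-fold, from 313 ± 12.9 to 11.4 ± 1.26 CPM (adjusted p = 5.91e-27), while the defensins DEFA4 (6.65 ± 0.11) and DEFA1 (8.71 ± 0.20) rose. In the interferon list 31 rose and 1 fell of 38 tested, 31 and 1 adjusted over the list alone (adjusted p = 1.49e-10). IRF1 rose 8.64-fold, from 18.7 ± 1.63 to 162 ± 1.59 CPM, the antiviral OAS3 10.5-fold and the proteasome subunits PSMB8 3.15-fold and PSMB9 11.3-fold.

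Among apoptosis regulators in NB4 20 rose and 5 fell of 35 tested, 20 and 5 adjusted over the list alone (adjusted p = 0.00285). BCL2A1 rose 65.5-fold, from 1.66 ± 0.287 to 109 ± 2.74 CPM, and its relative BCL2 fell 8.33-fold, from 44.2 ± 2.78 to 5.29 ± 0.935 CPM. Cholesterol synthesis followed with 20 rose and 1 fell of 23 tested, 21 and 1 adjusted over the list alone (adjusted p = 2.53e-08, and adjusted p = 0.0781 with an estimated correlation), HMGCS1 rising 2.08-fold and MVD 2.85-fold. Liver X receptor targets followed with 9 rose and 0 fell of 11 tested, 9 and 1 adjusted over the list alone (adjusted p = 0.000214), including FASN (0.97 ± 0.06), SCD (0.93 ± 0.05) and ABCA1 (1.37 ± 0.08). Of the known retinoic acid responsive genes 15 rose and 2 fell of 24 tested, 16 and 2 adjusted over the list alone (adjusted p = 1.15e-08). Of the genes of retinoid metabolism and transport 7 rose and 1 fell of 15 tested, 7 and 2 adjusted over the list alone (adjusted p = 0.00473, and adjusted p = 0.105 with an estimated correlation), with DHRS9 rising from 22.6 ± 1.09 to 216 ± 0.807 CPM. Of the retinoid receptors and co-regulators 10 rose and 2 fell of 16 tested, 10 and 2 adjusted over the list alone (adjusted p = 0.0228, and adjusted p = 0.103 with an estimated correlation). Fitted without the other lines, NB4 lost that call (adjusted p = 0.0548). NCOA3 rose 5.05-fold and PPARD, a fatty acid receptor, 2.05-fold. In MYC and ribosome biogenesis 3 rose and 20 fell of 28 tested, 3 and 20 adjusted over the list alone (adjusted p = 8.8e-05, and adjusted p = 0.0816 with an estimated correlation), and MYC fell 2.05-fold, from 989 ± 13.8 to 482 ± 1.11 CPM.

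Lists not called in NB4 began with gut homing, which had 5 higher and 1 lower of 8 (5 and 1 adjusted over the list alone, adjusted p = 0.107) and a median of 1.40, or 1.39 with bounds. Fitted without the other lines, NB4 gained calls, both higher, for gut homing (adjusted p = 0.0263) and NF-kB genes (0.00405). Skin homing had 2 higher and 5 lower of 11 (2 and 5 adjusted over the list alone, adjusted p = 0.505), where FUT7, an enzyme of selectin ligands, fell 2.87-fold. NF-kB and inflammatory genes had 12 higher and 7 lower of 24 (12 and 7 adjusted over the list alone, adjusted p = 0.174), where the chemokine CCL2 rose 117-fold, from 11.8 ± 0.250 to 1384 ± 79.1 CPM, and ICAM1 21.3-fold. T-helper cytokines and regulators had 3 higher and 8 lower of 19 (3 and 8 adjusted over the list alone, adjusted p = 0.235), where TNF fell 6.08-fold, from 421 ± 84.3 to 69.2 ± 4.74 CPM, and TGFB1 rose 2.12-fold. Myeloid identity had 6 higher and 5 lower of 11 (6 and 5 adjusted over the list alone, adjusted p = 0.928), where MPO, the myeloperoxidase of primary granules, fell 4.43-fold, from 7866 ± 178 to 1774 ± 67.2 CPM, and CSF3R, the receptor of granulocyte colony-stimulating factor, rose 5.42-fold. Coagulation and fibrinolysis had 5 higher and 4 lower of 15 (5 and 4 adjusted over the list alone, adjusted p = 0.978), where F3, the tissue factor that starts clotting, fell 9.78-fold and ANXA2, a receptor of plasminogen, 3.81-fold. The p53 targets had 6 higher and 2 lower of 17 (6 and 2 adjusted over the list alone, adjusted p = 0.336), with GADD45A at 2.09 ± 0.13.

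G1/S and DNA replication in NB4 had 7 higher and 19 lower of 40 (8 and 19 adjusted over the list alone, adjusted p = 0.163), with the inhibitor CDKN2D at 2.62 ± 0.10, and G2/M and mitosis had 10 higher and 2 lower of 29 (10 and 2 adjusted over the list alone, adjusted p = 0.182). Unfolded protein response genes had 3 higher and 9 lower of 20 (3 and 9 adjusted over the list alone, adjusted p = 0.0706), with XBP1 at -1.35 ± 0.06, and without control replicate 1 the list was called lower (adjusted p = 0.0476). Immediate early genes had 4 higher and 12 lower of 20 (4 and 13 adjusted over the list alone, adjusted p = 0.0653), with NR4A1 at -1.83 ± 0.20, and were called lower without control replicate 1 (0.000793) and with a replicate block (0.04997). T-cell activation had 5 higher and 6 lower of 23 (5 and 6 adjusted over the list alone, adjusted p = 0.579), T-cell identity 1 higher and 3 lower of 19 (1 and 2 adjusted over the list alone, adjusted p = 0.807), with CD4 at 0.61 ± 0.06, and the lymphoma markers 1 higher and 2 lower of 16 (1 and 2 adjusted over the list alone, adjusted p = 0.644), with SATB1 at -1.03 ± 0.09. B-cell identity had 3 higher and 1 lower of 7 (3 and 1 adjusted over the list alone, adjusted p = 0.478), epithelial identity 1 higher and 1 lower of 8 (1 and 1 adjusted over the list alone, adjusted p = 0.652), with KRT8 at 2.26 ± 0.15, and fibroblast identity 3 higher and 0 lower of 6 (3 and 0 adjusted over the list alone, adjusted p = 0.556). Signs differed between median, mean and test for skin homing (-0.42, 0.21, lower), the lymphoma markers (0.00, 0.13, lower), G1/S (-0.14, 0.06, lower) and myeloid identity (0.21, -0.46, lower). With an estimated correlation between genes, 4 of 8 list calls held in HH, 4 of 12 in Hut78 and 6 of 10 in NB4. Those were the retinoic acid responsive genes in all 3 lines, MYC and ribosome biogenesis in HH and Hut78, G1/S and G2/M in HH, interferon and liver X receptor genes in Hut78 and NB4, and the granulocytic, primary granule and apoptosis lists in NB4. By fry, whose p tests whether a list moves on balance 1 way and whose mixed p whether it changes in either direction, 18, 24 and 24 lists moved 1 way and 26, 27 and 27 changed in HH, Hut78 and NB4, without comparison to other genes.

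**Figure D4:**
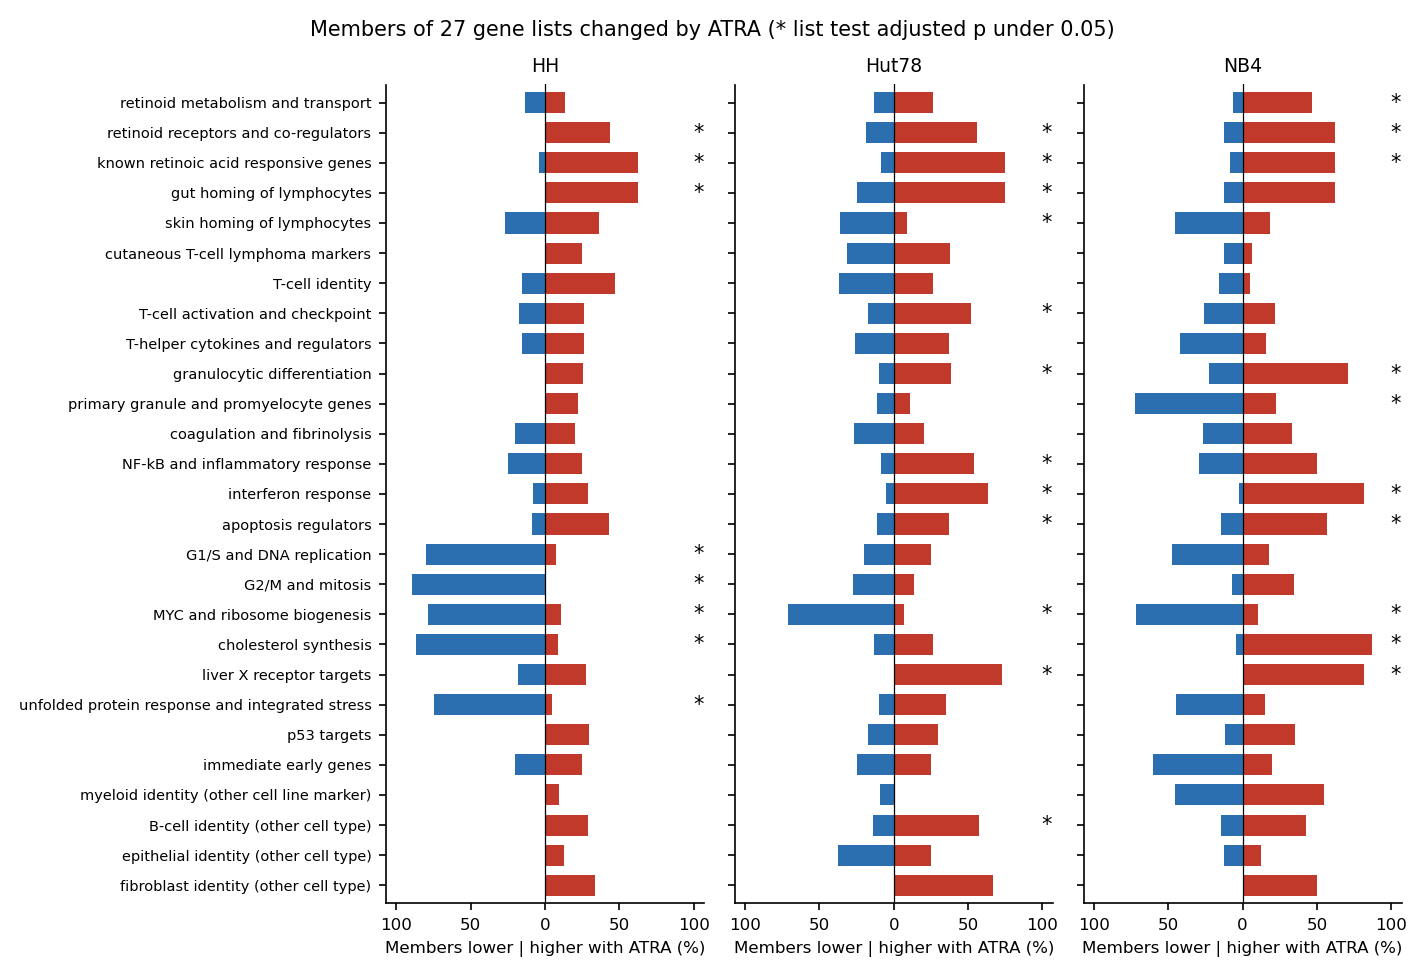
Percent of the tested members of 27 gene lists that were higher (red, to the right) or lower (blue, to the left) with ATRA in HH, Hut78 and NB4 (n = 2 libraries per group), with a star where camera's adjusted p passed 0.05. HH has 8 stars, Hut78 12 and NB4 10.

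HH and Hut78 come from the same kind of lymphoma, and their comparison asked where the response to ATRA differed between them. HH raised BSG and CDC34, which did not rise in Hut78. Hut78 raised ASB2, MAN1A1 and NECTIN1 far more than HH did. KLF2 rose in HH and fell in Hut78. By the test of the difference itself, 4217 genes responded differently, 2155 with the higher response in HH and 2062 in Hut78, and 920 of them by a log2 difference of 1 or more (654 and 266).

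The difference in log2 fold change, HH minus Hut78, was 4.58 ± 0.09 for BSG (adjusted p = 1.14e-26) and 2.91 ± 0.09 for CDC34. AHNAK, a large scaffold protein, differed by 3.31 ± 0.09, since it rose by 0.33 in HH and fell by 2.98 in Hut78 on the log2 scale. MYO1G, a myosin of blood cells, differed by 1.94 ± 0.07 and SELPLG by 2.41 ± 0.10, both with a rise in HH and a fall in Hut78. ASB2 differed by -3.88 ± 0.10 (adjusted p = 3.18e-23), MAN1A1, a mannosidase of the Golgi, by -3.26 ± 0.09 and the adhesion gene NECTIN1 by -3.39 ± 0.12. DUSP4, a phosphatase of MAP kinases, and PREX1 fell in HH and rose in Hut78, and differed by -2.72 ± 0.10 and -1.71 ± 0.07. ADA2 fell in HH and rose in Hut78 (-2.66 ± 0.12). KLF2 rose in HH (4.03 ± 0.32), fell in Hut78 (-4.03 ± 0.25) and differed by 8.06 ± 0.41 (adjusted p = 3.31e-16). Among the 13 fixed genes, HIC1 responded more in HH by 1.03 ± 0.11, RXRA differed by 1.00 ± 0.11 and RARA by -0.41 ± 0.09. RARG differed by 0.63 ± 0.24 (adjusted p = 0.0437), a call lost with DESeq2 (0.249), on TPM values with a pseudocount of 1 (0.107) or 0.1 (0.304), and without HH control replicate 2 (0.146), HH ATRA replicate 2 (0.238), Hut78 control replicate 1 (0.164) or Hut78 ATRA replicate 2 (0.134). With 0 counts in the HH controls, the test cannot weigh CYP26A1, CYP26B1, DHRS3, TGM2 or STRA6 between HH and another line. RARB and CD38 were not called (adjusted p = 0.0919 and 0.606).

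NB4 and HH were compared to ask which responses set the promyelocytic line apart from this lymphoma line. NB4 raised ALOX5AP and PLCB2, genes of leukocyte signalling, far more than HH did, and raised GNG2, which was not called in HH. HH raised BSG, NKD2 and GFI1, which fell in NB4. HMGCS1, of cholesterol synthesis, rose in NB4 and fell in HH. In all 5654 genes differed in response, 2837 higher in NB4 and 2817 higher in HH, and 1574 of them by a log2 difference of 1 or more (514 and 1060). On TPM values with a pseudocount of 1 the split was 2706 and 3598.

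GNG2, a G-protein subunit, differed by 5.97 ± 0.10 (NB4 minus HH, adjusted p = 9.16e-29), ALOX5AP, which leukotriene synthesis needs, by 6.82 ± 0.13, and PLCB2, a phospholipase, by 4.03 ± 0.10. SLA, an adaptor that dampens receptor signals, differed by 3.68 ± 0.08 and the kinesin KIF21B by 2.93 ± 0.08. BSG differed by -4.74 ± 0.09 (adjusted p = 1.23e-27) and AHNAK by -4.97 ± 0.11, since AHNAK fell by 4.64 in NB4 on the log2 scale. NKD2, an inhibitor of Wnt signalling, rose by 3.57 in HH and fell by 2.47 in NB4, a difference of -6.04 ± 0.16. GFI1 differed by -3.28 ± 0.09, TBC1D4 by -3.00 ± 0.09 and AFF2 by -4.06 ± 0.13, each with a rise in HH and a fall in NB4. HMGCS1 differed by 2.28 ± 0.08 (adjusted p = 5.17e-20), while the difference of the cholesterol list as a whole was not tested. Among the fixed genes ASB2 differed by 2.85 ± 0.12, RXRA by -0.98 ± 0.10 and HIC1 by 2.20 ± 0.24, which on TPM values with a pseudocount of 1 was 0.34 and not called (adjusted p = 0.0869). RARB differed by 5.18 ± 1.37 (adjusted p = 0.00265, or 0.169 without HH control replicate 2) and RARG by 1.80 ± 0.43 (0.000939, or 0.051 without NB4 ATRA replicate 2). CD38 was not called (adjusted p = 0.23).

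STRA6 and RARA gave weak calls between NB4 and HH. The fitted difference of STRA6 was -3.88 ± 1.47 (adjusted p = 0.041) and rests on 0 counts in the HH controls. On TPM values by limma-trend it changed its sign with a pseudocount of 1 (1.08, adjusted p = 2.48e-05). With a pseudocount of 0.1 it kept its sign but was not called (-0.40, adjusted p = 0.202). That call was lost with no filter (0.0516), with DESeq2 (0.0913), with a replicate block (0.0814), and without HH control replicate 1 (0.173), HH control replicate 2 (0.16), HH ATRA replicate 1 (0.107) or NB4 control replicate 2 (0.0576). RARA differed by 0.25 ± 0.09 (adjusted p = 0.032), a call lost with DESeq2 (0.0992), on TPM values with a pseudocount of 1 (0.151) or 0.1 (0.137), and without HH control replicate 1 (0.0882), HH ATRA replicate 2 (0.159), NB4 control replicate 2 (0.0979), NB4 ATRA replicate 1 (0.0626) or NB4 ATRA replicate 2 (0.0825).

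The comparison of NB4 with Hut78 set the promyelocytic line against the lymphoma line that induced CYP26A1 and DHRS3. NB4 raised TGM2, DHRS3 and HIC1 more than Hut78 did, and Hut78 raised ASB2, STRA6 and the vitamin D receptor VDR more. RCSD1 and FLOT1 rose in NB4 and fell in Hut78. In all 4511 genes differed in response, 2326 higher in NB4 and 2185 higher in Hut78, and 1330 of them by a log2 difference of 1 or more (661 and 669). On TPM values with a pseudocount of 1 the split was 2020.0 and 2863.

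TGM2 differed by 8.83 ± 0.96 (NB4 minus Hut78, adjusted p = 1.07e-08), HIC1 by 3.23 ± 0.22, DHRS3 by 2.98 ± 0.22 (adjusted p = 2.35e-12) and RARG by 2.42 ± 0.41. ASB2 differed by -1.03 ± 0.16, STRA6 by -0.90 ± 0.12 and CD38 by 0.79 ± 0.09, a call lost on TPM values with a pseudocount of 0.1 (adjusted p = 0.12). CYP26A1 differed by 1.75 ± 0.55 (adjusted p = 0.0139), a call lost on TPM values with a pseudocount of 1 (0.306) or 0.1 (0.139), and without Hut78 control replicate 1 (0.0507), NB4 control replicate 1 (0.0773) or NB4 control replicate 2 (0.0764). CYP26B1 (0.545), RARA (0.216), RARB (0.614), RXRA (0.985) and CRABP2 (0.958) were not called. GNG2 differed by 5.27 ± 0.10 (adjusted p = 8.83e-27), ALOX5AP by 6.44 ± 0.16 and PLCB2 by 4.91 ± 0.10. RCSD1 and FLOT1, of lipid rafts, rose in NB4 and fell in Hut78, and differed by 3.21 ± 0.08 and 3.43 ± 0.09. VDR differed by -3.95 ± 0.11 (adjusted p = 2.91e-23). LZTFL1 (-3.65 ± 0.12), the protease CTSH (-2.67 ± 0.10), GFI1 (-2.36 ± 0.08), NUCB2 (-1.96 ± 0.07) and HSPG2, the matrix protein perlecan (-2.95 ± 0.10), rose in Hut78 and fell in NB4.

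Genes changed the same way in all 3 lines were sought to find a response shared by lymphoma and leukemia lines. HIC1, ASB2, BHLHE40, SREBF1 and GPR35 rose in every line, and SLC7A5, which imports large amino acids, fell in every line. MYC also fell in all 3. In all 1426 genes changed the same way, 714 higher and 712 lower, against 196 and 153 if the lines were independent. By 2-fold or more there were 70 higher and 5 lower, against 3.81 and 0.190 if they were independent. On TPM values with a pseudocount of 1 the split was 448 higher and 662 lower.

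HIC1 had log2 fold changes of 3.77, 2.74 and 5.97 in HH, Hut78 and NB4, and ASB2 of 1.95, 5.83 and 4.80. In the same order they were 2.17, 2.17 and 1.91 for GALM, a sugar mutarotase, 1.42, 2.34 and 4.24 for the repressor BHLHE40, 1.38, 1.74 and 1.20 for SREBF1 and 4.94, 3.54 and 2.96 for GPR35. The adaptor SKAP2 gave 1.70, 1.58 and 2.14, the interferon-induced SAMD9L 1.28, 1.47 and 2.82, LSP1, an actin-binding protein of leukocytes, 1.00, 1.89 and 6.75, and HNRNPLL, a splicing factor of T cells, 1.05, 1.52 and 1.93. STING1, a sensor of cyclic dinucleotides, gave 1.95, 1.20 and 3.01, NOTCH2 0.94, 1.06 and 1.72, the lipid receptor GPR132 2.42, 1.22 and 1.79, ITGB7 1.33, 2.46 and 4.69, the tetraspanin CD53 1.14, 0.94 and 1.61 and ALOX5AP 0.94, 1.32 and 7.76. CYTH1 gave 0.89, 0.88 and 1.23 and NECTIN1 1.02, 4.42 and 1.72. SMG6, whose span overlaps HIC1, gave 2.59, 1.09 and 1.05. SLC7A5 fell by 2.05, 0.97 and 1.31 on the log2 scale, and MYC by 0.84, 0.51 and 1.04. The largest adjusted p of these 20 genes in any line was 1.27e-13, MYC aside. Among the 5 genes lower by 2-fold or more in all lines, chosen after their values were seen, were DDN, SEMA3G, TERT, which encodes the reverse transcriptase of telomerase, and TNFSF14.

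Pairs of lines shared more changed genes than independence gives, by Fisher's exact test over the 13668 genes (12 tests added after changed genes were seen, two-sided, BH-adjusted p of 1.39e-06 or lower). HH and Hut78 shared 1453 rises (781 expected) and 1315 falls (623 expected), NB4 and HH 1223 rises (929) and 1164 falls (746), and NB4 and Hut78 1329 rises (723) and 1310 falls (688). Of genes changed in both lines, 81.9% of 3379 moved the same way in HH and Hut78, 77.6% of 3402 in NB4 and Hut78 and 65.5% of 3645 in NB4 and HH. Across the 13668 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.18 (rho = 0.31) for HH and Hut78, 0.11 (0.14) for NB4 and HH and 0.25 (0.29) for NB4 and Hut78. Opposite changes of 2-fold or more in both lines were found for 28, 72 and 73 genes in HH and Hut78, NB4 and HH, and NB4 and Hut78, and in each of them the difference was called.

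**Figure D5:**
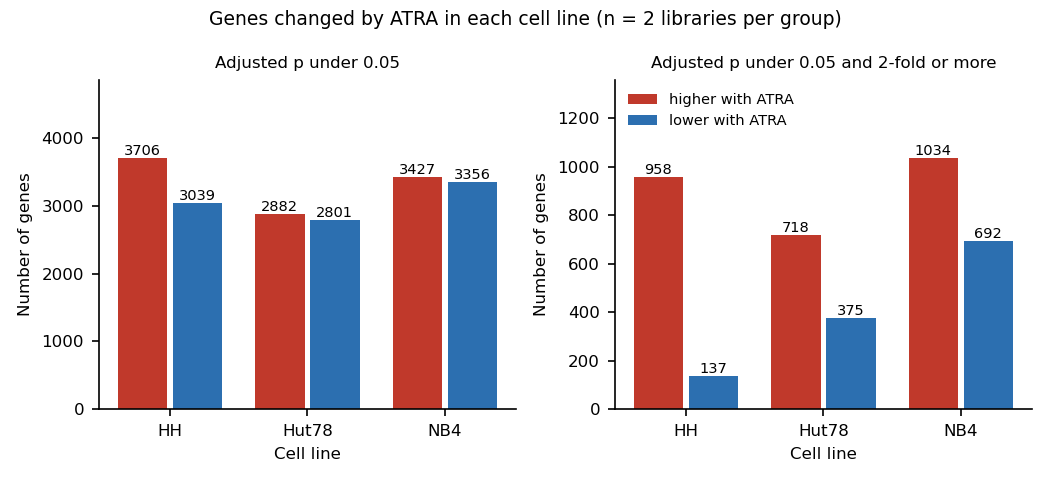
Number of genes higher (red) and lower (blue) with ATRA in HH, Hut78 and NB4 (n = 2 libraries per group), at an adjusted p of 0.05 (left) and at a change of 2-fold or more besides (right). At 2-fold or more, HH had 958 rises and 137 falls, Hut78 718 and 375, and NB4 1034 and 692.

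Controls of the 3 lines were compared for the genes that bind, carry and break down retinoids, to see what each line had before treatment. HH had the most RARA and NCOA1, and no counts of STRA6 or DHRS3. Hut78 had the most STRA6, DHRS3 and PML. DHRS9, an enzyme that oxidises retinol, and RBP4, which carries it in plasma, were highest in NB4. Of 31 members tested in both lists, 30 differed between some pair of lines, with 26 (HH and Hut78), 25 (NB4 and HH) and 25 (NB4 and Hut78) adjusted over the list alone. Of all 13668 genes, 79.6%, 80.6% and 79.4% differed between the same pairs of controls. A difference between lines was therefore not particular to these lists. Each line stands for itself, so a difference is between lines, not diseases.

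RARA stood at 106 ± 3.26 CPM in HH, 60.6 ± 1.12 in Hut78 and 40.4 ± 1.01 in NB4, and each pair differed (adjusted p = 5.38e-13 for HH and Hut78, 1.72e-18 for NB4 and HH, 5.6e-09 for NB4 and Hut78). RXRA stood at 104 ± 7.01, 39.4 ± 0.0809 and 109 ± 2.46 CPM in that order, lowest in Hut78. NCOA1 stood at 635 ± 13.4, 50.5 ± 0.396 and 26.9 ± 2.09 CPM (log2 difference 3.65 ± 0.06 between HH and Hut78). STRA6 had 0 counts in HH, 43.8 ± 0.980 CPM in Hut78 and 8.75 ± 1.08 in NB4 (adjusted p = 4.14e-20 between the last pair). DHRS3 had 0 counts in HH, 21.9 ± 1.47 CPM in Hut78 and 0.928 ± 0.325 in NB4. DHRS9 was at 0 in both lymphoma lines and at 22.6 ± 1.09 CPM in NB4, and RBP4 at 0 and at 4.82 ± 0.630. NRIP1 stood at 1.36 ± 0.247 CPM in HH and 0 in the other lines. PML stood at 34.1 ± 0.323, 144 ± 7.16 and 90.5 ± 0.971 CPM, RARG at 8.35 ± 0.879, 10.9 ± 0.968 and 0.608 ± 0.232, the retinal reductase RDH11 at 159.5 ± 2.86, 50.6 ± 0.882 and 64.98 ± 0.858, and FABP5 at 205 ± 5.45, 160.1 ± 5.27 and 111 ± 4.84. RARB, near 0 in each line, was called between no pair.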

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

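Chosen only after the result was seen were the tests of carried-over reads, of DNA background, of depth, of untreated cells and of reads running on from a neighbour. The tests of GC content and length and of silent genes were also added once the patterns had been seen, with their bounds written before their own results.

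All results here drew attention through a difference between cell lines under the same contrast, tested as the difference itself with edgeR. The response to ATRA differed in 4217 genes between HH and Hut78, in 5654 between NB4 and HH and in 4511 between NB4 and Hut78. For HH minus Hut78, the log2 differences of the genes with the higher response in HH were 4.58 for BSG, 3.31 for AHNAK, 2.91 for CDC34, 1.94 for MYO1G and 2.41 for SELPLG. Those with the higher response in Hut78 were -3.88 for ASB2, -3.26 for MAN1A1, -3.39 for NECTIN1, -2.72 for DUSP4, -1.71 for PREX1 and -2.66 for ADA2. The retinoid genes added 1.00 for RXRA and 1.03 for HIC1.

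For NB4 minus HH, the log2 differences were 5.97 for GNG2, 6.82 for ALOX5AP, 4.03 for PLCB2, 3.68 for SLA and 2.93 for KIF21B, all higher in NB4. Higher in HH were -4.74 for BSG, -4.97 for AHNAK, -6.04 for NKD2, -3.28 for GFI1, -3.00 for TBC1D4 and -4.06 for AFF2. The retinoid genes added 5.18 for RARB, 1.80 for RARG, 2.85 for ASB2 and 2.20 for HIC1. STRA6 passed at -3.88, a value that rests on 0 counts in the HH controls and is not taken as a difference. For NB4 minus Hut78, they were 5.27 for GNG2, 4.91 for PLCB2, 3.21 for RCSD1, 6.44 for ALOX5AP and 3.43 for FLOT1, higher in NB4, and -3.95 for VDR, -3.65 for LZTFL1, -2.67 for CTSH, -2.36 for GFI1, -1.96 for NUCB2 and -2.95 for HSPG2, higher in Hut78. The retinoid genes added 1.75 for CYP26A1, 2.42 for RARG, 2.98 for DHRS3, 8.83 for TGM2, -1.03 for ASB2 and 3.23 for HIC1.

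Genes of low abundance rose together in HH: the 1824 genes of 0.5 to 5 CPM had a median log2 fold change of 0.47, each of the 4 pairs of an ATRA and a control library gave 0.43 to 0.45, and Hut78 and NB4 gave 0.11 and 0.04. A trend in GC content and length was fitted on HH genes of 20 CPM or more, and the median stayed at 0.431 after its removal. That argues against a trend shared by genes of all levels as the whole cause. It cannot weigh a trend that acts only on genes of low abundance. Reads carried over from the other lines were argued against, since they give 1.91% of the summed rise. A background of DNA reads and a rise of transcription cannot be told apart: 101 genes of receptor and keratin-associated families that T cells do not use gained 20.4% as many CPM per kb as the low-abundance genes, between the bounds set for either answer. An effect of ATRA on many weakly expressed genes of HH stays open as a biological explanation; it was not tested.

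CYP26A1, CYP26B1 and DHRS3, raised in Hut78 and NB4, had 3, 0 and 1 counts in HH with ATRA. Too few counts were argued against, since the highest levels those counts allow are 2.51%, 1.15% and 0.250% of the lowest level with ATRA in the other lines. Untreated cells in the ATRA group were argued against, since 70 of 242 genes raised 2-fold or more in both other lines were raised in HH too (17.0 expected, Fisher's exact p = 1.32e-25). Genes silent in the HH controls rose less often: 19.5% of those under 0.5 CPM (26 of 133) against 40.4% of the others (44 of 109, Fisher's exact p = 0.000575, adjusted over 3 lines p = 0.00172), while the same split gave 39.0% and 45.0% in Hut78 (p = 0.585) and 35.6% and 40.5% in NB4 (p = 0.625). The odds ratios, 0.361 in HH, 0.783 in Hut78 and 0.813 in NB4, were not compared between lines, so a state particular to HH was not tested. A rise from under 0.5 CPM is also harder to call, and the HH libraries had the lowest depth. A lower rate of response of silent genes in HH stays open. It does not hold for every retinoid gene, as STRA6, also at 0 counts in the HH controls, was called higher in HH (at least 3.71-fold).

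CDC34, GZMM, BSG and HCN2, neighbours on chromosome 19, rose in HH and in neither other line, with the difference called for each gene against each line. For GZMM the size of that difference rests on 0 counts in the HH controls, and its change in NB4 was uncertain (0.60 ± 1.24). GC bias was argued against: 2076 other genes of like GC content (60.6% to 70.8%) had a median log2 fold change of 0.0856 in HH. For CDC34 and BSG, reads running on from a neighbour were argued against, since BSG lies after CDC34 on the strand and reached 19.9 times its level per kb. For GZMM and HCN2, such reads and a rise of their own cannot be told apart, as they reached 2.28% (GZMM) or less of the level per kb of the gene before them, and the table holds no reads across junctions. A shared switch of the region in HH stays open and was not tested. Runs of 4 neighbouring genes raised 2-fold or more, with overlapping runs counted apart, numbered 3 in HH, 7 in Hut78 and 15 in NB4. Such a run was therefore not particular to HH.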

How the results depend on the processing

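The counts over genes of 20 CPM or more and the block with the numbers of HH crossed were chosen after seeing the data. The numbers of changed genes kept within 1.5 times their main value with RLE size factors, no filter, DESeq2, a replicate block, TPM with either pseudocount, each line alone and the genes of 20 CPM or more. HH gave 6745 genes in the main setting, 5519 with DESeq2, 6509 with a replicate block, 6830 with the crossed block and 4968 among genes of 20 CPM or more. Hut78 gave 5683, 4165 with DESeq2 and 4010 among genes of 20 CPM or more, and NB4 gave 6783, 5408 and 4652. Leaving out 1 library gave 5575 to 5990 genes in HH, 4347 to 5296 in Hut78, 5664 to 5966 in NB4, 3401 to 4021 for HH minus Hut78, 4873 to 5285 for NB4 minus HH, 3799 to 4421 for NB4 minus Hut78, 1165 to 1390 in all 3 lines, and 8 to 8, 10 to 11 and 10 to 12 lists in HH, Hut78 and NB4. The retinoid genes that differed between controls numbered 30 to 31. A minimum fold of 2 lowered the counts by its own construction, to 1095 in HH, 1093 in Hut78, 1726 in NB4, 920 for HH minus Hut78, 1574 for NB4 minus HH, 1330 for NB4 minus Hut78 and 75 in all 3 lines. An estimated correlation left 4 lists in HH, 4 in Hut78 and 6 in NB4, and the cause was not tested. On TPM the share of rises in NB4 was 40.0% against 50.5% on counts, and the cause was not tested. The TPM values were not scaled by TMM, whose factors were 0.996 and 0.995 in the NB4 controls and 0.962 and 0.959 with ATRA. In Hut78 these factors also fell, from 1.06 and 1.05 to 1.04 and 1.02. With a pseudocount of 1 the median log2 fold change shifted by -0.0405 in NB4 and by 0.0037 in Hut78. The largest shift of a line's median log2 fold change between scalings was -0.0600, in NB4 on TPM with a pseudocount of 0.1. Of 451 results for single genes, 405 were called, and 365 of these kept their direction and their side of the threshold in every alternative that tested them. Of 5197 values under alternatives, 5034 kept both, 122 lost a call, 37 gained one and 4 changed sign. With TPM and a pseudocount of 1, the sign changed for the differences of STRA6 (-2.23 for HH minus Hut78 and 1.08 for NB4 minus HH), CYP26A1 (-0.21 for NB4 minus Hut78) and CYP26B1 (-1.82 for NB4 minus Hut78), genes near 0 in a control group, where a pseudocount of 1 shrinks the fold by its construction. Differences against HH for genes at 0 in its controls are limited by depth.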

Other observations

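The tests of Gene Ontology terms and of neighbouring genes were added once changed genes had been seen, and the bound for neighbouring genes was written before its own result. Gene Ontology terms were tested among genes changed 2-fold or more (2443 terms, one-sided Fisher's exact test, BH). In HH 0 terms were called among rises or falls, with 118 and 73 at an unadjusted p under 0.05. In Hut78, 50 terms were called among rises, with immune response (64 of 276 genes, adjusted p = 2.99e-21), interferon-gamma signalling (25 of 68, 2.58e-12) and antigen presentation by MHC class II (9 of 11, 5.91e-08), and 2 among falls, neuron differentiation (15 of 108, 0.000597) and axon guidance (15 of 160, 0.0419). In NB4, 153 were called among rises, with immune response (87 of 276, 7.29e-29) and neutrophil chemotaxis (26 of 50, 8.88e-14), and 23 among falls, with angiogenesis (31 of 202, 7.31e-05), immune response (36 of 276, 0.000206), inflammatory response (35 of 293, 0.00124) and defense response to bacterium (18 of 87, 0.000224).

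The authors' q-values under 0.05 numbered 4887 in HH, 3567 in Hut78 and 4890 in NB4, of which 4827, 3536 and 4847 genes were called here as well. In HH their calls were 2180.0 higher and 2707 lower, the opposite balance to the 3706 and 3039 here, and the cause was not tested. In Hut78 they were 1814 and 1753, and in NB4 2596 and 2294. Myeloid markers summed to 0.487 to 1.16 CPM in the HH libraries, 1.35 to 8.13 in Hut78 and 3795 to 9362 in NB4, and 9 of the 12 are held in another list. T-cell markers summed to 1663 to 2199 CPM in HH, 1860 to 2622 in Hut78 and 259 to 391 in NB4. Markers of other cells were present: fibroblast markers summed to 821 to 1149 CPM in HH, 295 to 430.4 in Hut78 and 6.98 to 15.3 in NB4, B-cell markers to 307 to 416, 115 to 269 and 11.4 to 26.5, and epithelial markers to 20.6 to 22.9, 97.1 to 164 and 22.6 to 37.4. Erythroid markers, not tested for change, stayed at 0.728 CPM or lower in every library.

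Neighbouring genes may respond together to ATRA, a hypothesis tested on 5015 adjacent pairs at least 5 kb apart without a shared symbol root, both raised 2-fold or more. It asked for more such pairs in every line than in any of 1000 shuffles among genes of like level, and HH did not meet it: 37 pairs, against a shuffled mean of 22.1 and a highest of 39 (permutation p = 0.003). Hut78 had 47 pairs (shuffled mean 13.6, highest 25) and NB4 70 (27.2 and 46), each at a permutation p of 0.001, the smallest the shuffles can give. For pairs both lowered 2-fold or more, there were 2 in HH (highest 4, permutation p = 0.0899), 13 in Hut78 (11) and 34 in NB4 (23). Over all adjacent pairs, overlapping genes included, there were 114 in HH (highest 77), 110 in Hut78 (47) and 198 in NB4 (85).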
